A study of Homo sapiens with 9 samples.

How the data were processed

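RNA of CL1-0 cells, a human lung adenocarcinoma line, was measured on 9 Affymetrix expression arrays, 3 from cells carrying a scramble shRNA and 3 from cells carrying each of 2 shRNAs against KSRP, called shKSRP-1 and shKSRP-2 here as in the labels. Groups and replicate numbers were taken from the sample titles. The labels call the samples biological replicates but do not say that they came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

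The deposited table holds log2 values, 1 per probe set and array. Per the labels, biotin-labelled cRNA was made from total RNA of puromycin-selected cells, and MAS5 is the only tool named in the submitters' processing notes, with no version and no role given. From the deposited values themselves, every probe set was centred on its median over the 9 arrays, since all 54675 probe sets have a median of exactly 0. The median of each array is also 0, and values run from -5.12 to 4.77. The base of the logarithm is not given in the sources used here and was taken as 2, so every log2 difference and fold rests on that reading. Centring removed the level of each gene, so neither how strongly a gene was expressed nor signal over background is known, and no genome build or coordinates are used. Subtracting a median per probe set leaves differences between arrays unchanged. However, 21384 probe sets hold the value 0 on 2 or more arrays, and why was not tested. The INHBE probe set is 0 on all scramble arrays, with an SD of 0. For such genes the spread within a group may be understated.

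Of the probe sets, 62 are array controls and were left out of all tests. Among the other 54613, 41091 carry exactly 1 gene symbol in the annotation used here, 1801 carry several and 11721 carry none. Symbols were looked up through gene identifiers in a RefSeq table of assembly GRCh38.p14, which was used for names only. It matched 41037 of the probe sets with 1 symbol and changed 0 of their symbols. The value of a gene was the mean over its probe sets with exactly 1 symbol, which gave 19775 genes, 9252 of them with 1 probe set and 10523 with several.

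The analysis was planned before the data were examined, for a table that keeps the signal level. The centred table forced 3 departures. The planned filter on dim genes, the planned choice of the brightest probe set per gene and the planned trend of variance with level all need that level. All genes were therefore tested, the mean over probe sets was used, and the trend was left off. Each of these settings had been planned as an alternative.

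Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit with a mean per group over all 9 arrays and eBayes, which left 6 residual degrees of freedom. The contrasts were shKSRP-1 minus scramble, shKSRP-2 minus scramble, the mean of both shRNAs minus scramble, and shKSRP-2 minus shKSRP-1. P-values were adjusted over all 19775 genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" are used of such genes. Errors given after ± are standard errors of the limma contrast unless SD is named. The number of arrays, 3 per group, limits the precision.

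Before the data were examined, 23 gene lists were fixed from textbook knowledge, with 631 distinct genes, of which 582 were measured. The 22 lists with at least 5 measured members were tested with limma camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. Limma fry was run beside it. Its directional p tests whether the genes of a list move on balance to one side, and its mixed p whether they change in either direction. Neither compares a list with other genes.

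Named genes follow a rule fixed at the same time. They are KHSRP, EGR3, which was chosen from an unchecked recollection of published work on these cells and is therefore no independent prediction, the 12 largest rises and 12 largest falls in the mean of both shRNAs among genes called to the same side with both, the 5 largest differences to each side between the shRNAs, and up to 4 members per list with the lowest p for the mean of both. ATF4, PHGDH, TRIB3, BST2, IFI35, EGR1, MKI67, MMP10, ARID3B, PRTG and DORIP1 were added after their values were seen.

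The replicate numbers met the criterion fixed for this check of pairing. It asks that the deviations of same-numbered arrays from their group means correlate above 0.1 in every pair. The numbers come from the sample titles. These correlations, taken across genes, lay between 0.36 and 0.78. Deviations also correlated between replicates 2 and 3 of different groups, at 0.35 to 0.52, while replicate 1 against replicates 2 or 3 gave -0.62 to -0.49. The first component of the deviations held 67.6% of the variance within groups, so the shared structure is mainly replicate 1 against replicates 2 and 3. Replicates 2 and 3 passed the criterion whether or not their numbers matched, so their numbers are not shown to pair the samples. A fit with the replicate number as a block, which leaves 4 residual degrees of freedom, stands beside results whose call it changes or whose count it moves by over 1.5 times.

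The comparisons share the scramble arrays. Chance values of this sharing were simulated 50 times from the residual spread of each gene with no effect. As a check for duplicated arrays, replicates within each group were compared. They shared between 1106 and 2136 identical values of 54675, and the SD of their difference ran from 0.159 to 0.52 log2.

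The fits were tested on simulated data with the real genes and residual spreads, with 200 genes changed in 5 runs. For shKSRP-1 against scramble, 48.1% of genes changed by 0.5 log2, 86.7% of those changed by 1 and 98.6% of those changed by 2 were recovered, and 5.4% of calls were false. For shKSRP-2 against scramble the shares were 50.6%, 86.4% and 98.6%, with 6.7% false calls. For the mean of both shRNAs, the recovered shares were 59%, 90.2% and 99.4%, with 5.4% false calls. The simulated noise was independent between genes and between arrays, as in the simulations of shared controls. It lacks the structure shared by arrays of a replicate number, so these shares may not hold for the real arrays.

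Other settings were quantile normalization, centring of each array on its median over tested genes, probe sets ending in _s_at or _x_at left out, every probe set on its own, variance trends on the mean of the centred values, only the 6 arrays of a comparison, the replicate block, each array left out in turn, a test against a fold of 1.2, and a minimum fold of 2. A batch term for replicate 1, replicates 2 and 3 alone, the probe set with the largest SD, and genes with an SD above the median were added after the data were seen.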

Results

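Expression was profiled in CL1-0 cells, a lung adenocarcinoma line of low invasiveness, after stable knockdown of KSRP. KSRP, the product of KHSRP, is an RNA-binding protein that promotes the decay of AU-rich mRNAs and the maturation of some microRNAs. Cells carrying shKSRP-1, cells carrying shKSRP-2 and cells carrying a scramble shRNA gave 3 arrays each. Values are log2 values centred per probe set, so that differences between groups are known but levels are not.

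The replicate 1 arrays stood apart from replicates 2 and 3 in every group. The dap control probe sets, which detect a bacterial RNA added before labelling, were lower in replicate 1 by log2 differences of -3.35 in scramble, -3.52 in shKSRP-1 and -2.91 in shKSRP-2. The 18S ribosomal RNA probe sets were higher in replicate 1 by 2.18, 2.05 and 2.34. The GAPDH 5' probe set minus its 3' probe set, a sign of RNA or cRNA length, was alike in replicate 1, at 1.21, 1.18 and 1.22. In replicates 2 and 3 it was -0.15 and -0.64 in scramble, -0.72 and -1.40 in shKSRP-1, and 0.11 and 0.00 in shKSRP-2. ACTB showed the same order, with -0.63 and -0.95, -1.07 and -1.89, and -0.11 and -0.15.

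**Figure D1:**
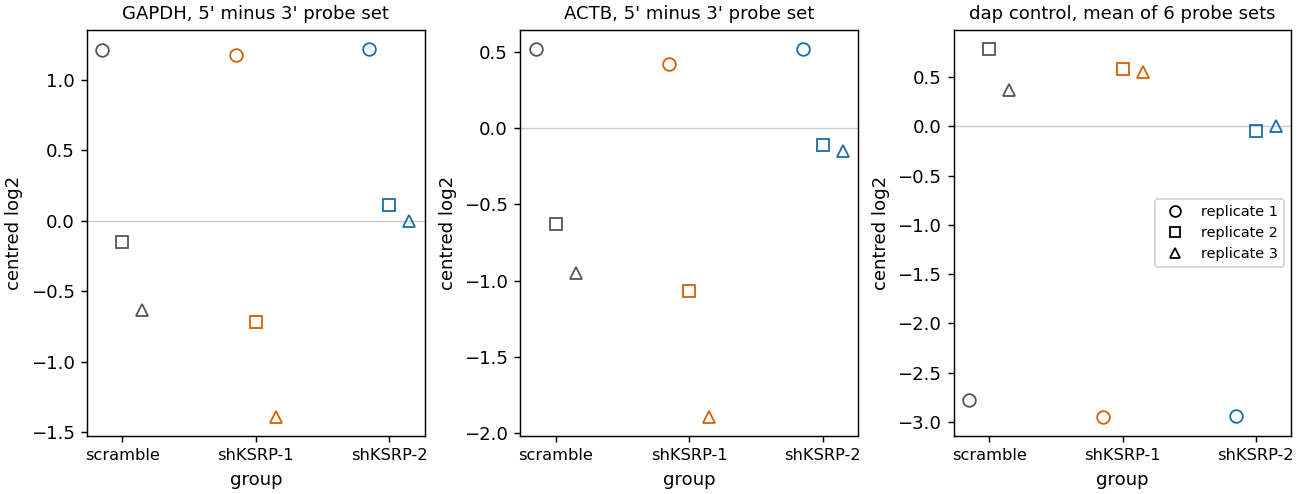
Centred log2 values per array for the GAPDH and ACTB 5' minus 3' probe sets and for the mean of 6 dap control probe sets, by group, with each replicate as its own symbol. The dap values of replicate 1 lie between -2.95 and -2.77 while those of replicates 2 and 3 lie between -0.05 and 0.79, and the 5' minus 3' values of the shKSRP-1 arrays of replicates 2 and 3 are the lowest.

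KHSRP, the target of both shRNAs, was lower in all 6 knockdown arrays than in any scramble array. Its mean over 4 probe sets was 1.33, 0.94 and 0.76 in the scramble arrays, -0.15, -0.05 and 0.02 with shKSRP-1, and -0.26, -0.20 and -0.32 with shKSRP-2. KHSRP fell by 1.07 ± 0.13 with shKSRP-1 (adjusted p = 0.000612) and fell by 1.27 ± 0.13 with shKSRP-2 (adjusted p = 0.000767). The shRNAs did not differ detectably in KHSRP (log2 difference -0.20 ± 0.13, adjusted p = 0.318). The probe sets of the gene moved unequally. The KHSRP probe set with the largest change was 4.70-fold lower with shKSRP-1 and 6.48-fold lower with shKSRP-2, and the next was 2.55-fold and 3.01-fold lower. The remaining KHSRP probe sets gave log2 differences of -0.27 and -0.43 with shKSRP-1 and -0.51 and -0.29 with shKSRP-2, with adjusted p between 0.227 and 0.626. All 4 end in _s_at or _x_at, which marks probe sets that can detect more than a single transcript. Within replicate 1 the KHSRP difference was -1.48 with shKSRP-1 and -1.59 with shKSRP-2, and within replicates 2 and 3 it was -0.87 and -1.11. The KHSRP paralogues FUBP1 and FUBP3, which bind single-stranded nucleic acids through the same kind of domain, did not pass the test with either shRNA as means over their probe sets. FUBP1 differed from scramble by 0.28 ± 0.12 with shKSRP-1 (adjusted p = 0.173, and 0.00757 with a replicate block) and by -0.47 ± 0.12 with shKSRP-2 (adjusted p = 0.0531, and 0.00111 with the block). FUBP3 differed by 0.37 ± 0.13 with shKSRP-1 (adjusted p = 0.0797, and 0.049 with the block) and by -0.30 ± 0.13 with shKSRP-2. These means hide probe sets of opposite sign. Those of FUBP1 ran from -0.69 to 1.37 with shKSRP-1 and from -1.18 to 0.29 with shKSRP-2. Those of FUBP3 ran from -0.23 to 0.96 with shKSRP-1, and from -0.46 to -0.13 with shKSRP-2, where the sign was shared.

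EGR3, an immediate early transcription factor chosen from a recollection of published work on these cells and so no independent prediction, rose with both shRNAs. Its single probe set averaged -1.87 ± 0.21 in scramble, 0.78 ± 0.28 with shKSRP-1 and -0.04 ± 0.17 with shKSRP-2 (SD, n = 3). EGR3 rose 6.27-fold with shKSRP-1 (2.65 ± 0.16 log2, limma adjusted p = 1.6e-05) and 3.55-fold with shKSRP-2 (1.83 ± 0.16, adjusted p = 0.00041). In the mean of both shRNAs EGR3 rose by 2.24 ± 0.14 (adjusted p = 7.5e-05), the largest rise among genes called to the same side with both. Within replicate 1 the rise was 2.55 and 1.86, and within replicates 2 and 3 it was 2.70 and 1.81.

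**Figure D2:**
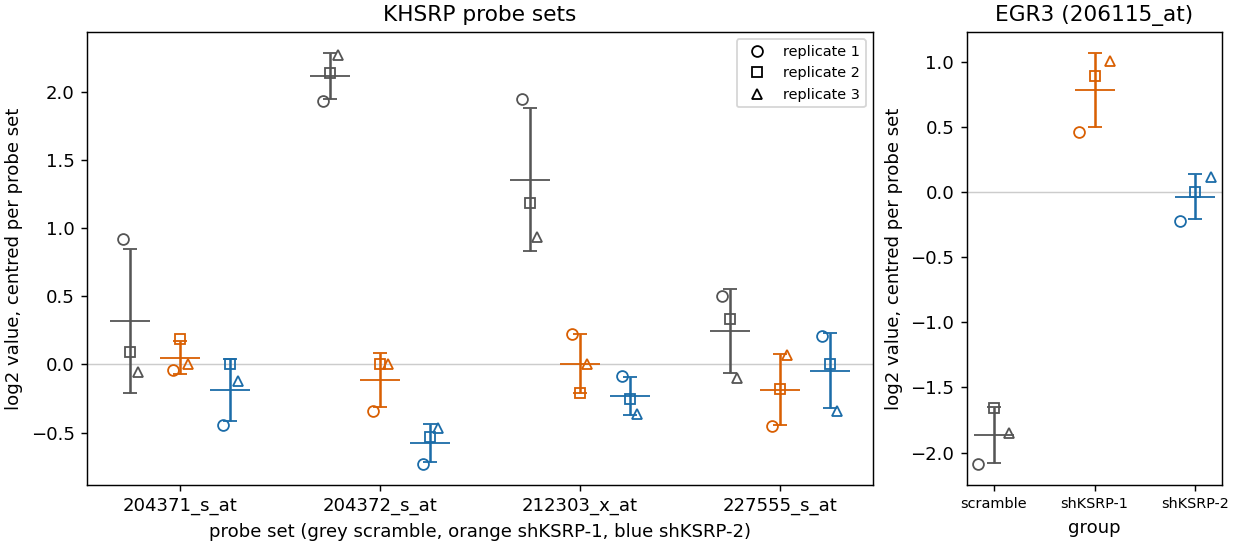
Centred log2 values per array for the 4 KHSRP probe sets and the EGR3 probe set, with the mean and SD of each group (n = 3). Scramble arrays lie above all knockdown arrays for the 2 KHSRP probe sets with the largest change, and below all of them for EGR3.

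The first comparison asked what shKSRP-1 changed against scramble. Many genes of amino acid supply and its stress response fell, 20 of 29 on the list, and 10 of 27 immediate early genes rose. As lists they were called at the preset correlation but not with an estimated correlation (adjusted p = 0.0526 and adjusted p = 0.0698 with an estimated correlation). STC2, a secreted glycoprotein induced by stress, fell by 2.24 ± 0.08 (log2 difference ± SE, n = 3 arrays per group), SLC7A5, a transporter of large neutral amino acids, fell by 1.76 ± 0.08, and SHMT2, a mitochondrial enzyme of serine and glycine metabolism, fell by 1.24 ± 0.07. The transcription factor ATF4, which drives many genes of this response, fell by 0.77, and its targets PHGDH and TRIB3 fell by 1.95 and 1.43. The larger falls included LAMP3, a lysosomal membrane protein, which fell by 3.46 ± 0.14, DHRS2, a short-chain dehydrogenase, which fell by 3.10 ± 0.07, and CSTA, a cysteine protease inhibitor, which fell by 3.07 ± 0.17. CTCFL, a germline paralogue of the insulator protein CTCF, fell by 3.09 ± 0.27, PPM1E, a protein phosphatase, fell by 2.41 ± 0.18, and INHBE, an activin subunit, fell by 2.36 ± 0.08. Rises included IFI44L, an interferon-induced gene, at 2.14 ± 0.17, CREB5 at 1.85 ± 0.08 and CREBRF, a regulator of the CREB3 family, at 1.72 ± 0.07.

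By list, 20 of 29 measured members of the amino acid and unfolded protein stress list fell with shKSRP-1, 2 rose and 7 did not pass the test. Adjusted over the list alone, 21 fell and 3 rose. DNAJB9, a chaperone of the endoplasmic reticulum, went against the list and rose by 1.84 ± 0.14. The list stood lower than other genes (camera adjusted p = 6.0e-08, and adjusted p = 0.0526 with an estimated correlation). Of 27 measured immediate early genes, 10 rose and 2 fell, with the same counts adjusted over the list alone. JUN, an AP-1 subunit, rose by 1.34 ± 0.11, EGR1 by 1.33, the growth-arrest factor KLF10 by 1.01 ± 0.09, FOS by 0.63 ± 0.08 and the orphan nuclear receptor NR4A2 by 1.41 ± 0.06 (list adjusted p = 0.000144, and adjusted p = 0.0698 with an estimated correlation). Of 31 genes of hypoxia and glycolysis, 10 fell and 1 rose, and 15 fell and 2 rose adjusted over the list alone. BNIP3, a mitochondrial protein of mitophagy, fell by 2.06 ± 0.09 and the glycolytic enzyme PGAM1 fell by 0.75 ± 0.07 (adjusted p = 0.00269 for the list, and adjusted p = 0.144 with an estimated correlation). Of 25 NRF2 and redox genes, 8 fell and 0 rose, with 9 falls adjusted over the list alone, among them TALDO1, which fell by 0.75, and NQO1, a quinone reductase, which fell by 0.59 (adjusted p = 0.0019, and adjusted p = 0.0573 with an estimated correlation).

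The interferon response list was lower with shKSRP-1 (adjusted p = 0.0158, and adjusted p = 0.175 with an estimated correlation). Of its 34 measured members 11 fell and 2 rose, and adjusted over the list alone 14 fell and 5 rose. IFI35 fell by 1.88, BST2, a membrane protein that tethers virions, fell by 1.58, and HERC6 fell by 0.96 ± 0.12, while IRF7, a regulator of interferon genes, rose by 0.84 ± 0.14. Of 38 cell cycle genes 14 fell and 2 rose, and adjusted over the list alone 17 fell and 3 rose. CCNB1, the mitotic cyclin B1, fell by 0.64 ± 0.08 and the survivin gene BIRC5 fell by 0.65 ± 0.08 (adjusted p = 0.015, and adjusted p = 0.0766 with an estimated correlation). Cholesterol synthesis genes were higher, with 7 of 21 up and 1 down, and 8 up and 1 down adjusted over the list alone. INSIG1, a sterol sensor, rose by 1.15 ± 0.15, MSMO1, a sterol oxidase, by 1.05 ± 0.10 and SQLE, squalene epoxidase, by 0.70 ± 0.08 (adjusted p = 0.0014, and adjusted p = 0.0573 with an estimated correlation). Of 24 microRNA biogenesis genes 8 rose and 3 fell, and 9 rose and 3 fell adjusted over the list alone. LIN28B, which blocks let-7 maturation, rose by 0.78 ± 0.10 and TNRC6A, a silencing scaffold, by 0.68 ± 0.08 with 6 probe sets between -0.01 and 1.02, while RAN, the nuclear transport GTPase, fell by 1.10 ± 0.11 (adjusted p = 0.0019, and adjusted p = 0.175 with an estimated correlation). Ribosomal protein genes had a mean of 0.07 with 2 of 34 up and 0 down, and 0 either way adjusted over the list alone (adjusted p = 0.0123, and adjusted p = 0.144 with an estimated correlation). The other 13 of the 22 lists were not called.

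In total shKSRP-1 changed 3607 genes, with 1411 higher and 2196 lower, 385 of them by at least 2-fold. After quantile normalization the split was 1389 higher and 1577 lower. With the replicate block the count was 6172, and without scramble replicate 2 it was 2363. The means of the stress list were -0.70 within replicate 1 and -0.65 within replicates 2 and 3, and those of the immediate early list 0.34 and 0.40. After quantile normalization the stress list had a mean of -0.42 against -0.66 before it, and the interferon list -0.13 against -0.25. The shKSRP-1 arrays of replicates 2 and 3 also had the lowest 5' signal of GAPDH, -0.72 and -1.40, beside these groups.

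The second comparison asked what shKSRP-2 changed against scramble. Some immediate early genes rose here too, as did 7 of 30 extracellular proteases and inhibitors. TRIM71, an RNA-binding ubiquitin ligase and let-7 target, rose by 1.94 ± 0.10, INHBE rose by 2.59 ± 0.08, CSTA, which had fallen with shKSRP-1, rose as well, BEX4 rose by 1.63 ± 0.08, and IL18, an inflammatory cytokine, rose by 1.88 ± 0.15. TFPI2, a secreted protease inhibitor, rose by 1.85 ± 0.13, MMP10, a stromelysin, by 2.05 and the cell cycle inhibitor CDKN1A by 1.11 ± 0.09. SNAPC1, a subunit of the small nuclear RNA transcription complex, fell by 2.35 ± 0.10, PIBF1 fell by 1.85 ± 0.18, CNOT6, a deadenylase, fell by 1.29 ± 0.19 and MOB1B, a Hippo pathway protein, fell by 1.07 ± 0.19.

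Of the 27 immediate early genes, 10 rose and 2 fell with shKSRP-2, and 14 rose and 2 fell adjusted over the list alone. JUN rose by 0.69 ± 0.11, KLF10 by 0.71 ± 0.09, EGR1 by 0.73 and FOS by 0.62 ± 0.08, while NR4A2 fell by 0.31 ± 0.06 (list adjusted p = 3.9e-06, and adjusted p = 0.0745 with an estimated correlation). Of 30 extracellular proteases and inhibitors 7 rose and 1 fell, with the same counts adjusted over the list alone. The falling member was SERPINE2, a serine protease inhibitor, which fell by 0.78 ± 0.09 with probe sets at -1.63 and 0.06, and TIMP1, an inhibitor of matrix metalloproteinases, rose by 0.59 ± 0.11 (list adjusted p = 0.0033, and adjusted p = 0.0745 with an estimated correlation). Integrin and focal adhesion genes had a mean of 0.18, with 2 of 27 up and 1 down both over all genes and adjusted over the list alone. Mesenchymal markers had a mean of 0.13, with 5 of 29 up and 2 down, or 8 up and 3 down adjusted over the list alone. Their adjusted p were 0.0084 and 0.0269, and adjusted p = 0.248 and adjusted p = 0.268 with an estimated correlation. The fibrillar collagens COL5A1 and COL5A2 rose by 0.69 ± 0.13 and 0.68 ± 0.07, while the actin-binding CALD1 fell by 0.64 ± 0.07 and the caveolar protein CAV1 fell by 0.39 ± 0.08.

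The interferon list was higher with shKSRP-2, with 3 of 34 up and 0 down, and 4 up adjusted over the list alone. BST2 rose by 1.22 and ISG20, an exonuclease, by 1.07 ± 0.09 (adjusted p = 0.0084, and adjusted p = 0.164 with an estimated correlation). The amino acid and unfolded protein stress list was also higher, with 4 of 29 up and 0 down, and 7 up adjusted over the list alone. STC2 rose by 0.52 ± 0.08 and DNAJB9 by 1.34 ± 0.14 (adjusted p = 0.0084, and adjusted p = 0.164 with an estimated correlation). TGF-beta targets had 4 of 24 members up and 0 down, and 6 up adjusted over the list alone. PMEPA1, a feedback inhibitor of this pathway, rose by 0.48 ± 0.11 and the basement membrane collagen COL4A2 by 0.65 ± 0.13 (adjusted p = 0.0081, and adjusted p = 0.0745 with an estimated correlation). Cell cycle genes were lower, with 9 of 38 down and 2 up, and 16 down and 6 up adjusted over the list alone. The proliferation marker MKI67 fell by 0.74, CCNB1 fell by 0.62 ± 0.08 and MCM3, a replicative helicase subunit, fell by 0.47 ± 0.07 (adjusted p = 0.0081, and adjusted p = 0.0745 with an estimated correlation). Of 38 mRNA decay genes 4 fell and 0 rose, and 6 fell adjusted over the list alone (adjusted p = 0.0033, and adjusted p = 0.248 with an estimated correlation). Of 34 splicing factors 1 fell and 0 rose by either adjustment (adjusted p = 0.0084, and adjusted p = 0.175 with an estimated correlation). The other 12 lists were not called. With the replicate block the AU-rich mRNAs (mean 0.16, adjusted p = 0.0617, and 0.0294 with the block) and cholesterol synthesis (mean 0.17, adjusted p = 0.124, and 0.0172 with the block) joined them.

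In total shKSRP-2 changed 1515 genes, with 752 higher and 763 lower, 103 of them by at least 2-fold. The count was 3623 with the replicate block and 2362 after quantile normalization. It was 715 and 758 without scramble replicates 2 and 3, and 729 and 703 without shKSRP-2 replicates 2 and 3. Within replicate 1 and within replicates 2 and 3, the list means were 0.0934 and 0.206 for the stress list, 0.0997 and 0.216 for integrins and focal adhesion, 0.079 and 0.159 for mesenchymal markers, 0.145 and 0.263 for TGF-beta targets, and 0.214 and 0.157 for the interferon list. The 5' signal of GAPDH moved with these groups as well, at 0.11 and 0.00 in shKSRP-2 against -0.15 and -0.64 in scramble for replicates 2 and 3.

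The labels give both shRNAs the same genotype, so the genes changed to the same side by both were counted. These were 424 genes, 197 higher and 227 lower, and 11 of them changed at least 2-fold with each shRNA. Beside EGR3 and DNAJB9, the largest rises in the mean of both shRNAs were those of GPR137C at 1.48 ± 0.15, DNM3, a dynamin, at 1.34 ± 0.13, CREB5, an AP-1 related transcription factor, at 1.29 ± 0.07, C2orf92 (1.86 ± 0.09 with shKSRP-1 and 0.54 ± 0.09 with shKSRP-2), TRIM71 at 1.17 ± 0.08 and CREBRF at 1.13 ± 0.06. WEE1, the kinase that restrains entry into mitosis, rose by 1.12 ± 0.20, BEX4 by 1.11 ± 0.07, GPR137B, a lysosomal membrane protein, by 1.09 ± 0.07 and VGLL3, a cofactor of TEAD factors, by 1.08 ± 0.15. The largest falls were those of DHRS2, which fell by 2.02 ± 0.06, the neurofilament NEFH, which fell by 1.63 ± 0.10, SNAPC1, which fell by 1.52 ± 0.09, and TMEM268, which fell by 1.31 ± 0.19. KHSRP itself fell by 1.17 ± 0.11, BZW2 fell by 1.12 ± 0.06, RAB26, a vesicle GTPase, fell by 1.10 ± 0.06, FAM169A fell by 1.05 ± 0.17, the noncoding RNA NEXN-AS1 fell by 1.01 ± 0.08, PDGFRL fell by 0.99 ± 0.10 and FAM216A fell by 0.98 ± 0.09. RAB8B, a GTPase of membrane traffic, fell by 1.31 ± 0.26 (adjusted p = 0.015), and its call was lost without scramble replicate 2 (adjusted p = 0.0835) or replicate 3 (adjusted p = 0.078). Of these 24 genes 12 have several probe sets, and the probe sets of 0 of them disagreed in sign.

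Independent lists of the same sizes would share 53.7 higher and 84.7 lower genes. A further 258 genes were called with both shRNAs in opposite directions, where 138 would be shared by independent lists. They make up 37.8% of all genes called with both. Since calls in opposite directions also exceeded the value for independent lists, an excess over it does not by itself show a shared effect. Across genes, which are not independent replicates, the log2 differences of the shRNAs correlated at r = 0.070 (Spearman 0.115), while unchanged groups against shared controls gave 0.502 in the simulations. The covariance was 0.00569, against 0.0113 simulated from the residual spread of each gene and 0.00481 from its spread after the replicate block. The difference, -0.00557 or 0.000886, thus changes sign with the spread used. Shifts shared by arrays of a replicate number cancel in these log2 differences, so the simulated 0.0113, which counts them, is too high. With 3 scramble arrays the controls could not be split, so part of the excess of shared calls may come from the shared controls. In 50 simulations of unchanged groups the highest number of genes called with both was 0. These runs held no changed genes, so they cannot size what shared controls add where genes do change. The shared count was 1163 with the replicate block, which kept all 424, and 717 after quantile normalization. It was 183 and 214 without scramble replicates 2 and 3, 274 without shKSRP-1 replicate 2, and 211 and 203 without shKSRP-2 replicates 2 and 3.

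**Figure D3:**
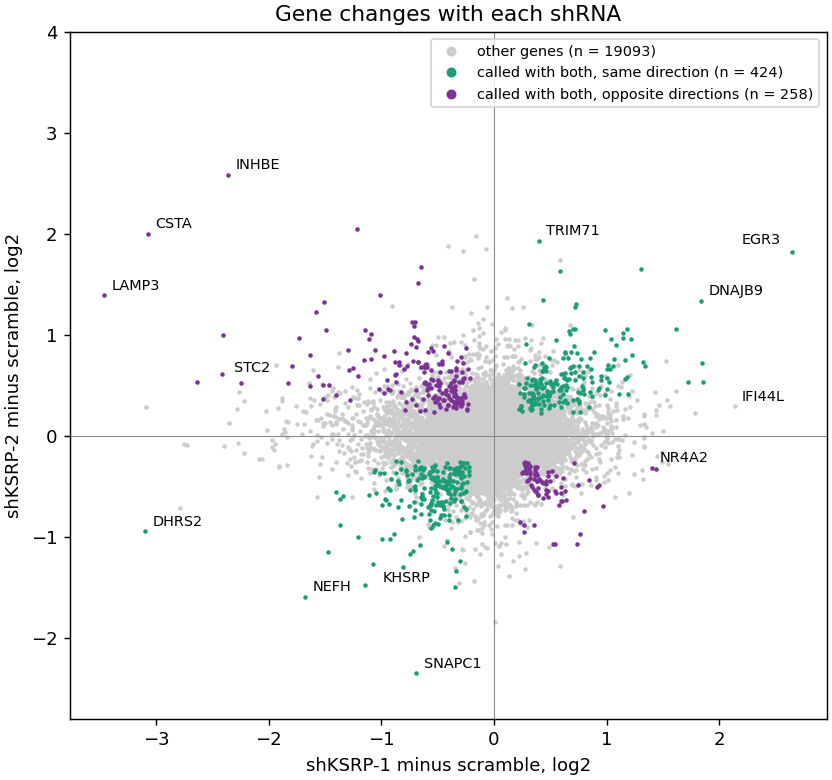
Log2 difference from scramble of each of 19775 genes with shKSRP-1 (horizontal) and shKSRP-2 (vertical). Green points are the 424 genes called with both to the same side, purple points the 258 called in opposite directions, and EGR3, DNAJB9, KHSRP and NEFH lie far from 0 on the diagonal while CSTA, INHBE and LAMP3 lie in the upper left.

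The genotype comparison took the mean of both shRNAs against scramble. Immediate early genes and cholesterol synthesis genes were higher, and cell cycle genes were lower. Of 27 immediate early genes 10 rose and 0 fell, and 11 rose and 3 fell adjusted over the list alone. EGR3, which is no independent prediction, is a member of this list. The list had a mean of 0.38 but a median of 0.18, and medians of 0.12 with shKSRP-1 and 0.33 with shKSRP-2. JUN rose by 1.02 ± 0.09, EGR1 by 1.03, KLF10 by 0.86 ± 0.08, FOS by 0.63 ± 0.07 and NR4A2 by 0.55 ± 0.05, the last of which had moved in opposite directions (list adjusted p = 3.6e-08, and adjusted p = 0.0472 with an estimated correlation). Of 38 cell cycle genes 10 fell and 1 rose, and 11 fell and 2 rose adjusted over the list alone. CCNB1 fell by 0.63 ± 0.07, BIRC5 fell by 0.48 ± 0.07, MCM3 fell by 0.44 ± 0.06 and MKI67 fell by 0.64, while CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 0.71 ± 0.08 (adjusted p = 0.0026, and adjusted p = 0.0472 with an estimated correlation). Without probe sets ending in _s_at or _x_at the cell cycle call was lost (adjusted p = 0.054). Of 21 cholesterol synthesis genes 5 rose and 0 fell, and 6 rose and 1 fell adjusted over the list alone. INSIG1 rose by 1.06 ± 0.13, MSMO1 by 0.56 ± 0.09 and SQLE by 0.45 ± 0.07 (adjusted p = 0.0013, and adjusted p = 0.0472 with an estimated correlation). With shKSRP-2 alone the cholesterol list was not called, with 2 of 21 up and 0 down (camera adjusted p = 0.124, and 0.0172 with the replicate block). The rises of MSMO1 and SQLE came mostly from shKSRP-1, with differences of shKSRP-2 minus shKSRP-1 of -0.96 and -0.50. For MSMO1 that difference is nearly its whole rise with shKSRP-1, so no rise with shKSRP-2 is shown.

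A further 3 lists were called at the preset correlation. The amino acid and unfolded protein stress list was lower, with 10 of 29 down and 2 up, and 11 down and 2 up adjusted over the list alone, although its means with the individual shRNAs had opposite signs, -0.66 and 0.17. Its mean over both shRNAs was -0.25, and -0.13 after quantile normalization. STC2, which had risen with shKSRP-2, fell by 0.86 ± 0.07 in this mean, SLC7A5 fell by 0.73 ± 0.07 and SHMT2 fell by 0.62 ± 0.06 (adjusted p = 0.000341, and adjusted p = 0.069 with an estimated correlation). MicroRNA biogenesis genes were higher, with 4 of 24 up and 1 down, and 5 up and 2 down adjusted over the list alone. LIN28B rose by 0.64 ± 0.09 and TRIM71 by 1.17, while RAN fell by 0.73 ± 0.10 (adjusted p = 0.0079, and adjusted p = 0.325 with an estimated correlation). TGF-beta targets had a mean of 0.09 with 1 of 24 up and 0 down by either adjustment, PMEPA1 with a rise of 0.63 ± 0.10 (adjusted p = 0.0271, and adjusted p = 0.11 with an estimated correlation). The microRNA biogenesis call was lost without scramble replicate 1 (adjusted p = 0.0852), with replicates 2 and 3 alone (0.141) and among genes with an SD above the median (0.0542). The call of TGF-beta targets was lost without scramble replicate 1 (adjusted p = 0.0716), without probe sets ending in _s_at or _x_at (0.0538) and among genes with an SD above the median (0.243).

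**Figure D4:**
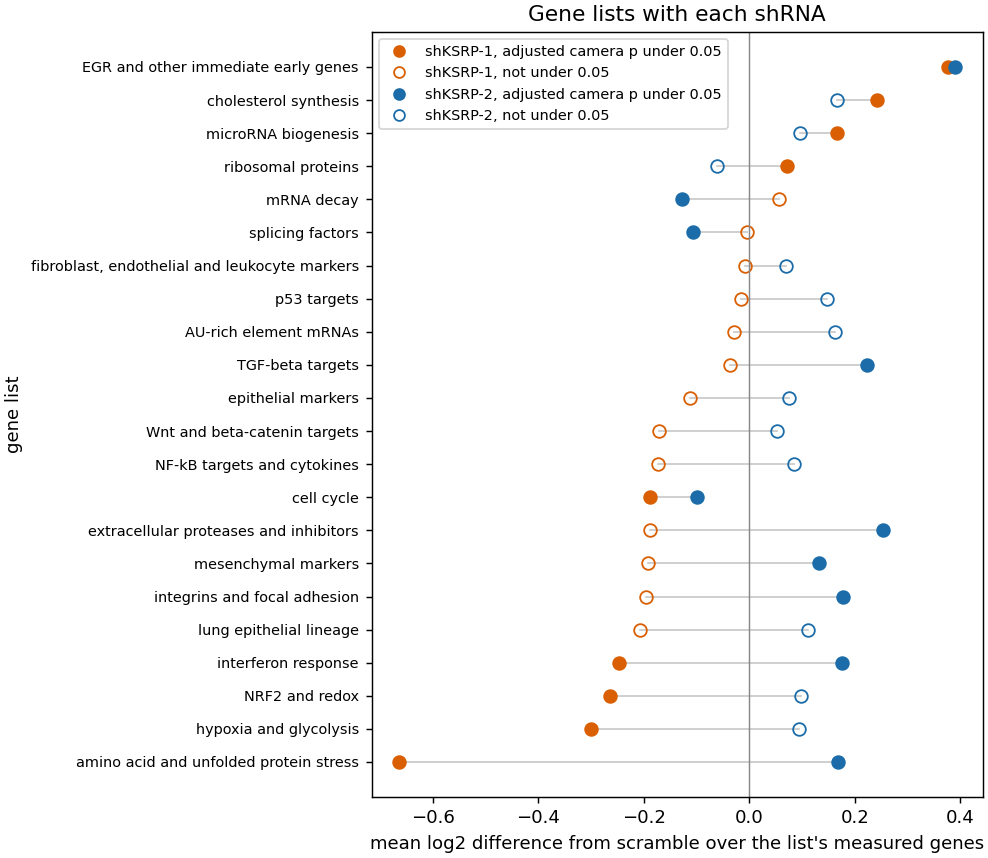
Mean log2 difference from scramble over the measured genes of each of the 22 tested lists, with shKSRP-1 in orange and shKSRP-2 in blue, and filled points where the adjusted camera p at the preset correlation was under 0.05. The immediate early list lies at 0.38 and 0.39 with both, while the amino acid and unfolded protein stress list lies at -0.66 with shKSRP-1 and 0.17 with shKSRP-2.

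The remaining 16 lists were not called in the mean of both shRNAs. AU-rich mRNAs, whose decay KSRP is known to promote, had 2 of 26 up and 1 down by either adjustment, with FOS and JUN up and the chromatin protein HMGB1 down (list adjusted p = 0.45). HMGB1 fell by 0.25, and its call was lost without any of the scramble arrays, without shKSRP-1 replicate 2 and without shKSRP-2 replicates 2 or 3 (adjusted p of 0.062 to 0.0954). ZFP36, a decay factor of such mRNAs, differed by 0.70 ± 0.21 (adjusted p = 0.071, and 0.000747 with the replicate block). Of 24 epithelial markers the adhesion molecule EPCAM rose by 0.57 ± 0.11, losing its call without scramble replicate 2 (adjusted p = 0.0565), and 0 fell by either adjustment, with CDH1, E-cadherin, at -0.36 ± 0.14 (adjusted p = 0.165, and 0.00891 with the block). Mesenchymal markers had 2 of 29 up and 3 down, or 3 up and 4 down adjusted over the list alone, with CALD1, which fell by 0.80 with 11 probe sets between -2.84 and 0.27, and LOX, a lysyl oxidase, which fell by 0.71. LOX fell by 1.67 with shKSRP-1 only, and differed by 0.24 with shKSRP-2 (adjusted p = 0.0808, and 0.0336 with the block). Proteases and inhibitors had 4 of 30 up and 2 down by either adjustment, with TFPI2 up by 0.89, TIMP1 up by 0.73 and the collagenase MMP1, which fell by 0.79. TFPI2 was called with shKSRP-2 only (1.85, against -0.07 with shKSRP-1). MMP1 was called with shKSRP-1 only (-1.24, against -0.34 with shKSRP-2, adjusted p = 0.193). With the replicate block it was called with shKSRP-2 as well (adjusted p = 0.0226). Integrin and focal adhesion genes had 1 of 27 up and 2 down by either adjustment, with CAV1, which fell by 0.58. Interferon genes had 4 of 34 up and 3 down, or 4 and 7 adjusted over the list alone, with IFI44L up by 1.22 and HERC6, which fell by 0.51 with probe sets at -1.04 and 0.02 and lost its call without scramble replicate 2 or 3 (adjusted p = 0.0824 and 0.0704). IFI44L rose by 2.14 with shKSRP-1 only, and differed by 0.29 with shKSRP-2 (adjusted p = 0.411). NF-kB targets had 1 of 26 up and 2 down by either adjustment, with IL18 up by 0.74 and NFKB1, which fell by 0.47. The rise of IL18 came from shKSRP-2, where it stood 2.29 above shKSRP-1.

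Wnt targets had 0 of 22 up and 1 down by either adjustment, the Wnt antagonist DKK1. DKK1 fell by 0.56 in this mean, but it fell by 1.63 with shKSRP-1 and rose by 0.50 with shKSRP-2. P53 targets had 2 of 24 up and 1 down by either adjustment, with ZMAT3 up by 0.65 and GADD45A, which fell by 0.72. Both changes came mostly from shKSRP-1, with differences of shKSRP-2 minus shKSRP-1 of -1.35 for ZMAT3 and 1.03 for GADD45A. No rise of ZMAT3 with shKSRP-2 is shown by these values. Hypoxia and glycolysis genes had 2 of 31 up and 5 down by either adjustment, with BNIP3, which fell by 1.15, and PGAM1, which fell by 0.37. These 2 falls also came mostly from shKSRP-1, with differences of shKSRP-2 minus shKSRP-1 of 1.83 and 0.76. For PGAM1 that difference is as large as its fall with shKSRP-1, so no fall with shKSRP-2 is shown. NRF2 and redox genes had 0 of 25 up and 3 down, or 1 and 6 adjusted over the list alone, with SRXN1, which fell by 0.54, TALDO1, which fell by 0.47, and NQO1, which fell by 0.40. Messenger RNA decay genes had 2 of 38 up and 3 down, or 3 and 4 adjusted over the list alone, with the deadenylase subunit PAN3 up by 0.34 and the exosome subunit EXOSC8, which fell by 0.53. Between the shRNAs PAN3 differed by -0.72 and EXOSC8 by 0.49, so both changes came mostly from shKSRP-1. No rise of PAN3 with shKSRP-2 is shown by these values. Splicing factors had 0 of 34 up and 4 down by either adjustment, with SF3B2, which fell by 0.40. Of 34 ribosomal protein genes 0 were called by either adjustment, with RPS24 at -0.29 ± 0.08 (adjusted p = 0.0657, and 0.0111 with the block). Lung lineage genes had 1 of 21 up and 1 down by either adjustment, and the falling gene was LAMP3, which fell by 1.03 in this mean but rose with shKSRP-2. Of 23 fibroblast, endothelial and leukocyte markers 0 were called by either adjustment, with PTPRC at 0.16 ± 0.06 and CD14 at 0.19 ± 0.07. Mean, median and camera direction differed in sign only in uncalled lists, among them the mesenchymal and integrin lists here.

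In the mean of both shRNAs 1819 genes were called, 696 higher and 1123 lower, 53 of them by at least 2-fold. The count was 4021 with the replicate block, 771 and 910 without scramble replicates 2 and 3, and 1167 without shKSRP-2 replicate 3. Within replicate 1 and within replicates 2 and 3, the immediate early list had means of 0.34 and 0.40 with shKSRP-1 and 0.35 and 0.41 with shKSRP-2, and the cell cycle list -0.17 and -0.20, and -0.13 and -0.08.

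The last comparison tested the difference between the shRNAs. The 4 largest differences were in genes called in opposite directions by the shRNAs. CSTA was higher with shKSRP-2 than with shKSRP-1 by 5.07 ± 0.17, INHBE by 4.95 ± 0.08, LAMP3 by 4.85 ± 0.14, PPM1E by 3.41 ± 0.18 and CTCFL by 3.38 ± 0.27. On the other side were CNOT6 at -1.88 ± 0.19, PIBF1 at -1.86 ± 0.18, IFI44L at -1.84 ± 0.17, SLC6A16, a transporter family member, at -1.83 ± 0.29 and MOB1B at -1.81 ± 0.19. Of the 29 stress genes 23 were higher with shKSRP-2 and 4 lower, with the same counts adjusted over the list alone. STC2 differed by 2.77 ± 0.08, SLC7A5 by 2.06 ± 0.08 and ATF4 by 0.88, while DNAJB9 differed by -0.50 ± 0.14 (list adjusted p = 8.4e-08, and adjusted p = 0.0552 with an estimated correlation). Of 34 interferon genes 16 were higher and 2 lower, and 18 and 2 adjusted over the list alone, with BST2 at 2.81 and IFI35 at 2.25 (adjusted p = 0.0011, and adjusted p = 0.0779 with an estimated correlation). The 2 lower interferon genes were IFI44L at -1.84 and IRF7 at -0.45. Of 31 hypoxia and glycolysis genes 13 were higher and 0 lower, or 18 and 1 adjusted over the list alone, with BNIP3 at 1.83 ± 0.09 (adjusted p = 8.8e-05, and adjusted p = 0.0774 with an estimated correlation). Of 27 integrin and focal adhesion genes 13 were higher and 1 lower, or 15 and 1 adjusted over the list alone, with ITGB5 at 0.41 ± 0.11 and CAV1 at 0.38 ± 0.08 (adjusted p = 0.0012, and adjusted p = 0.195 with an estimated correlation).

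Altogether 4869 genes differed, 2831 higher and 2038 lower with shKSRP-2, 626 of them by at least 2-fold. With the replicate block the count was 7637, and after quantile normalization the split was 1971 higher and 2172 lower. Of 22 lists 12 were called at the preset correlation and 0 with an estimated correlation, where fry called 18 by its directional and 22 by its mixed p. Quantile normalization ended the calls of NF-kB targets (adjusted p = 0.0779), cholesterol synthesis (adjusted p = 0.125) and microRNA biogenesis (adjusted p = 0.0807), and the call of cholesterol synthesis was also lost with the replicate block (adjusted p = 0.0989) and with array median centring (adjusted p = 0.0509). The shKSRP-1 arrays of replicates 2 and 3 had lower 5' signal than the shKSRP-2 arrays beside these groups, for GAPDH by the values -0.72 and -1.40 against 0.11 and 0.00.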

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

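The tests of the 5' signal, of the replicate 1 batch for the difference between the shRNAs, of labelling and hybridisation, and of regroupings that keep arrays of a replicate number apart were chosen after the result was seen.

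Between the shRNAs 4869 genes differed. Among the genes named by the rule or added to it, and among the lists, those whose difference between the shRNAs passed its own test are given here as shKSRP-2 minus shKSRP-1. Higher with shKSRP-2, by log2 difference, were CSTA (5.07), INHBE (4.95), LAMP3 (4.85), PPM1E (3.41), CTCFL (3.38), MMP10 (3.26), BST2 (2.81), STC2 (2.77) and IL18 (2.29). Smaller differences to this side were those of IFI35 (2.25), DHRS2 (2.16), DKK1 (2.13), SLC7A5 (2.06), COL4A2 (1.94), TFPI2 (1.92), LOX (1.91), TRIB3 (1.90) and BNIP3 (1.83). They were followed by PHGDH (1.81), TRIM71 (1.53), WIF1 (1.49), SHMT2 (1.25), ISG20 (1.202), BEX4 (1.04), GADD45A (1.03), HERC6 (0.91) and MMP1 (0.89). Next came ATF4 (0.88), FAM216A (0.84), CDKN1A (0.80), COL5A2 (0.80), PGAM1 (0.76), PDGFRL (0.73), RAN (0.73), KRT18 (0.56) and TALDO1 (0.55). Further genes higher with shKSRP-2 were SF3B2 (0.51), EXOSC8 (0.49), BZW2 (0.49), IL11 (0.48), NFKB1 (0.46), ITGB5 (0.41), NQO1 (0.39), CAV1 (0.38) and ABCA3 (0.36). The same side held BIRC5 (0.35), CALD1 (0.32), DCP1B (0.29), SRSF3 (0.28) and HMGB1 (0.25). Lower with shKSRP-2 were CNOT6 (-1.88), PIBF1 (-1.86), IFI44L (-1.84), SLC6A16 (-1.83), MOB1B (-1.81), NR4A2 (-1.72), SNAPC1 (-1.66), ZMAT3 (-1.35) and C2orf92 (-1.32). Smaller falls relative to shKSRP-1 were those of CREBRF (-1.18), CREB5 (-1.12), MSMO1 (-0.96), EGR3 (-0.82), RPL37 (-0.79), RPS27 (-0.76), FUBP1 (-0.75), PAN3 (-0.72) and DCP2 (-0.70). Below these came FUBP3 (-0.66), JUN (-0.65), EGR1 (-0.59), TNRC6A (-0.56), DNM3 (-0.55), SQLE (-0.50), DNAJB9 (-0.50), SKIL (-0.47) and IRF7 (-0.45). The lower side also held TP53INP1 (-0.41), SERPINE2 (-0.38), TCF7L2 (-0.35), DORIP1 (-0.34), PRTG (-0.31), KLF10 (-0.30) and ID2 (-0.28). With an estimated correlation 0 of the 12 lists called in this test kept their call. These lists, by mean log2 difference of shKSRP-2 minus shKSRP-1, had values of 0.32 for mesenchymal markers, 0.44 for extracellular proteases and inhibitors, 0.37 for integrins and focal adhesion, 0.42 for interferon response, 0.26 for NF-kB targets and cytokines, 0.83 for amino acid and unfolded protein stress. The others had values of -0.0767 for cholesterol synthesis, 0.39 for hypoxia and glycolysis, 0.36 for NRF2 and redox, -0.0706 for microRNA biogenesis, -0.18 for mRNA decay and -0.13 for ribosomal proteins.

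The first pattern is the difference between the shRNAs, seen in the stress genes STC2, SLC7A5 and ATF4 and in the interferon genes BST2 and IFI35. ATF4, BST2 and IFI35 were chosen after their values were seen. The interferon genes IFI44L (-1.84) and IRF7 (-0.45) and the stress gene DNAJB9 (-0.50) went the other way. Lower 5' signal in the shKSRP-1 arrays of replicates 2 and 3 is argued against as the whole cause, since of the 6473 genes called from those replicates alone 95.4% had the same sign in replicate 1, where GAPDH 5' signal was alike, with a median difference of 0.44 against 0.48. With the replicate block and GAPDH 5' minus 3' as a covariate, 4995 genes differed against 7637 with the block alone, 3576 of them to the same side among the 4869, whose median difference was 0.55 with the covariate and 0.53 without it, so calls were lost while the median size was kept. A deeper KHSRP knockdown by either shRNA is argued against, since 37.8% of the genes called with both went in opposite directions. A shift shared by the replicate 1 arrays cancels by design, since each group holds such an array. A difference confined to the replicate 1 arrays is argued against, since 6473 genes differed within replicates 2 and 3 alone, which hold no array of that batch. What stays open is off-target silencing by either shRNA, the place of insertion or the selection of each stable pool, none of which the design separates from the shRNA.

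The second pattern is the rise of immediate early genes such as EGR3, JUN, EGR1 and KLF10 with both shRNAs. A shift shared by the replicate 1 arrays cancels by design here too. A rise confined to those arrays is argued against, since the mean of the list was at least 0.335, and at most 0.412, in both batches with both shRNAs. Low values in the scramble arrays and a rise in the knockdown arrays cannot be told apart, since both shRNAs were compared with the same control group and there is no second one. The mean difference of the list between the shRNAs, 0.0126 over 6 members higher and 7 lower of 27, decides nothing here. Loss of KSRP, which promotes decay of such mRNAs, stays a candidate explanation, although the list of AU-rich mRNAs was not called in the mean of both shRNAs (mean 0.07, 2 of 26 higher and 1 lower, adjusted p = 0.45), as does a difference in growth or handling of the scramble cells.

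The third pattern is the place of the replicate 1 arrays. The dap control RNA, which is not cell RNA, was lower in replicate 1 in every group, with the smallest difference, -2.91 log2, in shKSRP-2, so a difference in labelling or hybridisation may account for it. No biological explanation was tested.

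The counts were set beside other splits of the arrays. For shKSRP-1 only 1 of 10 splits gave as many genes (3607, highest other 0), for shKSRP-2 also 1 of 10 (1515, highest other 0), between the shRNAs also 1 of 10 (4869, highest other 0), and 10 splits are too few for a share under 0.05. For the mean of both shRNAs 3 of 100 regroupings of the 9 arrays gave as many genes (1819, highest other 3733), and for genes changed to the same side 3 of 100 (424, highest other 2093). These regroupings ignore the replicate numbers, among which replicate 1 stands apart. Of 100 regroupings that keep arrays of a replicate number apart, 6 gave as many genes for the mean of both (1819, highest other 4885). For the same side 6 did so too (424, highest other 2613), so neither share is under 0.05. The other 5 of these each took all arrays of shKSRP-1 or of shKSRP-2 as the control group. They thus hold real differences between the groups, and their share cannot decide about chance, which is not excluded. This points to a structure of the samples in which each group stands apart. With a control group mixed from several groups, the highest counts were 348 and 0 in 89 regroupings.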

How the results depend on the processing

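The batch term for replicate 1, replicates 2 and 3 alone, the probe set with the largest SD and the genes with an SD above the median were chosen after the data were seen.

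KHSRP, as a mean or a single value per gene, and EGR3 kept their direction and their call under the settings that gave a value. With every probe set on its own, KHSRP ran from -2.23 to -0.27 with shKSRP-1 and from -2.70 to -0.29 with shKSRP-2, and 2 of its 4 probe sets did not pass with either. EGR3 ran from 2.24 to 2.69 in the mean of both shRNAs. With 1 array left out, the gene value of KHSRP ran from -1.20 to -0.91 with shKSRP-1 and from -1.39 to -1.11 with shKSRP-2, and EGR3 from 2.13 to 2.34.

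With 1 array left out, the genes changed ran from 2363 to 3669 with shKSRP-1, from 703 to 1859 with shKSRP-2, from 771 to 2156 in the mean of both shRNAs and from 3569 to 5016 between the shRNAs. Genes changed to the same side by both ran from 183 to 486, and the lists called in the mean of both from 4 to 6. The lowest counts against scramble came without scramble replicate 2, except for shKSRP-2 alone, whose lowest came without shKSRP-2 replicate 3.

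In the order shKSRP-1, shKSRP-2, mean of both, between the shRNAs and same side with both, the counts were 6172, 3623, 4021, 7637 and 1163 with the replicate block, and 6395, 3860, 4234, 7811 and 1275 with the batch term. Both fits remove variance shared by arrays of a replicate number, which leaves a smaller residual. Every probe set on its own gave 7305, 2728, 3160, 10192 and 772, over more features tested. A test against a fold of 1.2 gave 1049, 274, 212, 1742 and 46 by its stricter construction. A minimum fold of 2 left 385, 103 and 53 genes against scramble and 11 to the same side with both. Replicates 2 and 3 alone gave 2892 with shKSRP-2, 2775 in the mean of both and 758 to the same side. Quantile normalization gave 2362 with shKSRP-2 and 717 to the same side, and the cause was not tested.

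Of the lists, 3 were called in the mean of both with an estimated correlation, 10 by the directional and 20 by the mixed p of fry, which do not compare a list with other genes. FUBP1 reversed, from -0.10 to 0.65 (adjusted p = 0.0117), with the probe set of the largest SD. Its 4 probe sets ran from -0.93 to 0.65 in the mean of both shRNAs, so the gene value averages probe sets of opposite sign. For the other tests of single named genes, in the mean of both shRNAs or, for the 10 genes chosen by it, in the difference between the shRNAs, 1052 of 1143 with 1 array left out kept their direction and call, 76 lost the call and 15 gained it. Under the other settings 1138 kept them, 46 lost and 54 gained the call. For single lists in the mean of both shRNAs 196 of 198 kept them with 1 array left out and 212 of 220 under other settings, and the others lost the call. An estimated correlation ended all 9 list calls with shKSRP-1, all 10 with shKSRP-2 and all 12 between the shRNAs.

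An offset of 32, filters on level and the brightest probe set need a signal level and were not run, and the robust setting was run without lists. KHSRP has no value without probe sets ending in _s_at or _x_at. Signal over background is not known from centred values, so which genes lay near background cannot be said.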

Other observations

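The test of let-7 targets was set down before its result was seen, but the rise of TRIM71 and LIN28B that prompted it was found in these data.

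TRIM71 rose by 0.40 with shKSRP-1 and 1.94 with shKSRP-2, and LIN28B by 0.78 and 0.49. Both are known let-7 targets, and KSRP is known to promote the maturation of let-7, so lower let-7 activity may raise such mRNAs. A list of 30 other let-7 targets, of which 26 were measured, had a mean log2 difference of 0.122 in the mean of both shRNAs, with 6 members higher, 1 lower and a camera p of 0.00553 (0.0618 with an estimated correlation). The list mean was 0.17 with shKSRP-2 and 0.07 with shKSRP-1, and only the former passed camera unadjusted at 0.05, which it did not with an estimated correlation (0.0627). Whether the shRNAs differ in this list was not tested. ARID3B rose by 0.78, PRTG by 0.92 and DORIP1 by 0.62, chosen after their values were seen, while NAP1L1 fell by 0.33 and HMGA2 differed by -0.13 (adjusted p = 0.317). The hypothesis thus rests on some of the members, and let-7 itself was not analysed here.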
